A study of Rattus norvegicus with 12 samples.

How the data were processed

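Total RNA of rats given lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that is sensed through Toll-like receptor 4, was compared with control RNA on 2-colour arrays. That the RNA came from blood is given by the series title alone. The 12 arrays hold 6 rats, 3 labelled 2 h and 3 labelled 6 h. Each rat was hybridised against a control pool of its own time on 2 arrays, which the labels call fluor (control pool in channel 1, LPS in channel 2) and flip (the channels exchanged). The 2 arrays of a rat hold the same pair of RNA samples, so they were averaged and the rat was the replicate (n = 3 per time). The control pool counts as 1 control sample: tests of a mean ratio against 0 leave out its own spread, and the difference between 6 h and 2 h also holds any difference between the pools. The rats labelled 2 at the 2 times were treated as different samples, though the labels do not say whether they are 1 animal.

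The deposited values are 1 log2 ratio of the channels per probe and array, per the file headers and the values. The log base was settled from the values: among ratios under 5, the power of 2 of each value was a whole multiple of 0.0001 (tolerance 0.05 of that step) in 100% of values on every array, against 8.56% to 15.0% for the other bases and for the inverse ratio. The dyes, the scanner, the background correction and the normalization are not given in the sources used here. Array medians lay between -0.020 and 0.0083 and array standard deviations between 0.27 and 0.48, so the arrays had been centred near 0 before deposit, by a method that stays unknown. The table had 0 missing values. On each array 242 to 298 probes shared 1 repeated value (344 probes on any array, 39 of these on a named gene, and 80 on all 12). No intensities were at hand to show which spots lay above background. The number of arrays limits the precision.

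The direction of the ratios is likely, not settled. A rule fixed before the data were examined asked whether the fluor and flip arrays of each rat correlate above 0 (already turned) or below 0 (not turned) in all rats, and otherwise gave no direction. Pearson correlations over all probes were 0.09, 0.25 and -0.23 in the 2 h rats and 0.14, 0.07 and -0.05 in the 6 h rats, so the rule did not decide. In departure from it, the values were used as deposited and read as LPS over control pool, on a basis chosen after seeing the data. Of 28 textbook LPS-induced genes 8 were measured. Of these, 6 had a mean above 0 at both times, 5 (Il1b, Il1r2, Irf1, Lcn2 and Zfp36) lay above 0 on all 12 arrays, fluor and flip alike, and 0 were past the threshold below 0. Sod2 lay above 0 on 10 arrays, Tnf on 8 and Nfkbia on 3. Lcn2 is numbered 2 probes after Csnk2b, which had far larger ratios (means of 4.27 at 2 h and 5.10 at 6 h). With neighbouring probes subtracted Lcn2 was at 0.48 at 2 h and 0.34 at 6 h. Il1b averaged 3.23 on the fluor arrays and 2.71 on the flip arrays. Rat means as deposited had a mean correlation of 0.538 within a time and 0.394 between times, a gap of 0.144. With the flip arrays multiplied by -1 both correlations were higher (0.602 and 0.580) and the gap was 0.0222. Either gap was the largest of the 10 splits of the rats. Probe counts, camera calls, list counts over all genes, named genes and the gene families of the closing part were recomputed with the flip arrays multiplied by -1. So were the correlation and shared calls of the 2 times. Fry, the counts adjusted over a list alone, the self-test, the layout and the splits of the rats were not. A limma test against 0 of the mean of the 6 rats, with the flip arrays multiplied by -1, passed 2768 of 7200 probes, 50 of them at least 2-fold. These are dye effects if the deposited direction holds, and otherwise they hold the response to LPS.

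Probes were named from the platform annotation of 2007 with symbols updated through gene identifiers in the GRCr8 gene table. Of 7200 probes, 4190 had 1 symbol (4184 with an identifier in that table), 46 had several and 2964 had none; only those with 1 symbol were named. They gave 3939 genes, 236 of them with more than 1 probe, whose values were averaged. Names rest on the annotation, and no clone was sequenced or probe matched to a genome here.

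Rat means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3), all 6 rats in 1 model of group means with 4 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The contrasts were 2 h against 0, 6 h against 0, and 6 h minus 2 h. Counts of probes come from the fit of all probes, and values of genes from the fit of gene means. Errors beside values are standard deviations over 3 rats, and standard errors (SE) for 6 h minus 2 h. On simulated changes in 7200 probes, the share recovered at a log2 size of 0.25, 0.5, 1 and 2 was 52%, 92%, 100% and 100% at 2 h. It was 68%, 92%, 96% and 100% at 6 h, and 30%, 86%, 96% and 100% for 6 h minus 2 h. Of unchanged probes 0.0563%, 0.113% and 0.157% were called. The simulated noise was normal, independent between probes and the same on both arrays of a rat, so the simulated dye part cancelled. A spread of the control pools was not simulated. These shares check the fit in that setting and are no error rates of the calls on the real arrays.

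Of 25 fixed gene lists, covering inflammatory, metabolic and cell type markers, 24 had at least 5 measured members and were tested with camera (preset correlation 0.01) in each of the 3 contrasts. Adjustment was over all 72 tests. Camera with an estimated correlation and fry stand beside it. Genes were named by a fixed rule: the 10 with the largest mean in each direction among those past the threshold with the same sign on all arrays of the group (for 6 h minus 2 h, every 6 h rat beyond every 2 h rat), up to 4 members of each list past the threshold with the largest absolute means, and a short set of LPS response genes in any case, of which Il1b, Tnf, Sod2 and Nfkbia were measured. A gene outside the rule is named only as a list member or where said.

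Alternatives were centring, scaling and quantile normalization of the arrays, fluor or flip arrays alone, all arrays with a dye term and the rat as a random block, omission of the flatter probes, robust spread, each time fitted alone, each rat left out, 1 probe per gene, a 1.5-fold minimum and an estimated correlation. Those added after seeing the data were flip arrays multiplied by -1, omission of probes at the repeated value, and subtraction of neighbouring probes. Neighbours were taken by probe number, since the print order is not given in the sources used here. A filter on missing values was planned and is void, since no value was missing. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6).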

Results

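Gene expression in the blood of LPS-treated rats was measured with 7200 probes on 12 arrays, at 2 h in 3 rats and at 6 h in 3 that were treated as different rats. Each value is a log2 ratio to the control pool of the same time, averaged over the fluor and flip arrays of a rat. Positive values are read as higher after LPS. This direction is likely, from the textbook LPS-induced genes and not from stated dyes: Il1b, Il1r2, Irf1, Lcn2 and Zfp36 were above 0 on all 12 arrays, and no measured gene of that list was past the threshold below 0. Nfkbia, of the same list, was above 0 on 3 of 12 arrays, and Lcn2 is numbered near a far brighter change, as described above. With the flip arrays multiplied by -1, 63 of the 174 calls on named genes took the other sign, and 11 of 78 at 2 h, 11 of 78 at 6 h and 0 of 18 between the times passed the threshold with the same sign, while 2 at 2 h and 11 at 6 h passed with the other. That setting keeps only what differs between the fluor and flip arrays of a rat as deposited. If the deposited direction holds, a response alike on both arrays falls to near 0 there, so a call lost there is not weakened by it. A call kept there then belongs to a gene whose 2 arrays differ. Every rank by size below holds for the values as deposited. The comparisons ask which transcripts differed from control at 2 h, which at 6 h, and which differed between the times.

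At 2 h the largest rise among named genes with the same sign on every array belonged to Csnk2b, the regulatory subunit of casein kinase 2, at 4.27 ± 0.68 (SD, n = 3; 19.3-fold; adjusted p = 0.000149). Il1b, the cytokine interleukin-1 beta, rose by 3.90 ± 0.31 (14.9-fold; adjusted p = 6.7e-06). S100a9, a calcium-binding protein abundant in neutrophils, rose by 2.98 ± 0.53 (7.90-fold; adjusted p = 0.000432), and Anxa1, an anti-inflammatory annexin, by 2.65 ± 0.58 (6.30-fold; adjusted p = 0.0012). Among the genes that fell were the ribosomal protein gene Rps6 (-1.13 ± 0.23, adjusted p = 0.00066), the elongation factor Eef1a1 (-1.11 ± 0.11, adjusted p = 7.0e-05) and the actin-binding thymosin Tmsb10 (-1.07 ± 0.10, adjusted p = 0.000241). None of these 7 passed with the flip arrays multiplied by -1: Csnk2b stood at 0.45, Il1b at 0.30, S100a9 at 0.14, Anxa1 at 0.32, Rps6 at -0.0031, Eef1a1 at 0.08 and Tmsb10 at -0.05.

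The next largest rises at 2 h were those of Snx12, a sorting nexin (1.82 ± 0.07), Prdx5, a peroxiredoxin (1.48 ± 0.29), Tf, which encodes transferrin (1.44 ± 0.41), Rnf112 (1.28 ± 0.13), the aldolase gene Aldoc (1.25 ± 0.08) and the cytochrome P450 gene Cyp2f4 (1.19 ± 0.15). Rnf112 is numbered 4 probes after Csnk2b, and with neighbouring probes subtracted its mean was 1.13. The other large falls were those of Mss51 (-1.04 ± 0.35), the glutathione transferase Gstt1 (-0.88 ± 0.28), the proteasome subunit Psma1 (-0.84 ± 0.14), the biliverdin reductase Blvra (-0.83 ± 0.17), Eva1b (-0.82 ± 0.12) and the class II genes RT1-Db1 (-0.82 ± 0.07) and RT1-DMb (-0.81 ± 0.01). These 20 genes had adjusted p of at most 0.0468 in 18 of 19 alternatives. The other, with the flip arrays multiplied by -1, is the other reading of the direction and no test of robustness. In it only Snx12 (0.63), Tf (0.35) and Psma1 (-0.39) passed, the highest adjusted p was 0.999, and Eef1a1, Gstt1 and Blvra took the other sign.

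Of 5 measured proinflammatory cytokine genes at 2 h only Il1b rose. Tnf stood at -0.0037 ± 0.0624 (adjusted p = 0.948). Among 8 chemokine genes Ccl6 (0.40 ± 0.14) and Cx3cl1 rose while Ccl5, a chemoattractant of T cells (-0.67 ± 0.30), and Ccl9 (-0.29 ± 0.12) fell; 3 rose and 2 fell when adjusted over the list alone. Of 8 anti-inflammatory and feedback regulators 3 rose, namely Anxa1, the decoy receptor Il1r2 (0.62 ± 0.09) and the phosphatase Dusp1 (0.62 ± 0.34). Dusp6 fell (-0.27 ± 0.07), with its 2 probes at -0.53 and -0.0089. The list of NF-kappaB and AP-1 factors also holds genes of neither family, Cebpb, Cebpd and Ier2 among them. Of its 11 measured genes Fosl2 (1.00 ± 0.30) and Cebpd rose and Ier2 fell, and Nfkbia stood at 0.01 ± 0.06 (adjusted p = 0.821). Of 18 interferon-stimulated genes 3 rose (Rsad2 0.80 ± 0.30, Ifitm3 0.41 ± 0.06 and Irf1 0.21), while Ifi27 and Ifi27l2b fell. Of 8 eicosanoid and nitric oxide enzymes Arg2, Alox5 and Ptger4 rose and Gch1 (-0.50 ± 0.20) and Pla2g2a fell, with 4 up and 2 down when adjusted over the list alone. Pla2g2a stood at 0.017 on the flip arrays alone, which is the mean of the repeated values of those arrays (-0.22, -0.047 and 0.31). Its probe thus held no measured ratio there, and its fall rests on the fluor arrays. Ptger4 stood at -0.0061 on the fluor arrays alone. Of the 6 measured MHC class I and immunoproteasome genes 0 passed limma's threshold at 2 h, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05).

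Stress and oxidative defence genes that passed at 2 h all rose, 7 of 18, among them Gadd45g (0.47 ± 0.06), the glutathione peroxidase Gpx1 (0.46 ± 0.22) and the thioredoxin reductase Txnrd1 (0.40 ± 0.04); camera gave adjusted p = 0.0558, which misses the threshold, and 7 rose and 1 fell when adjusted over the list alone. Of the 18, 3 rose and 2 fell with the flip arrays multiplied by -1. Sod2, the mitochondrial superoxide dismutase, stood at 0.06 ± 0.09 (adjusted p = 0.377). Of 10 adhesion and proteolysis genes the metalloproteinase inhibitors Timp2 (1.18 ± 0.05) and Timp1 (0.22 ± 0.09) rose. Of 12 glycolysis genes the glucose transporters Slc2a3 (0.78 ± 0.33) and Slc2a1 and the hexokinase Hk1 rose, with Slc2a1 at -0.0057 once neighbouring probes were subtracted. Of 7 apoptosis regulators Bcl2l1 (0.44 ± 0.11), Mcl1 and Tnfrsf1b rose. Of 15 proliferation genes Ccnd1, Fen1 and Plk1 rose and Pcna (-0.34 ± 0.03) and Cdk1 (-0.20 ± 0.04) fell, with 3 up and 3 down when adjusted over the list alone.

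Cytosolic ribosomal protein genes were lower at 2 h as a group: of 44 measured, 26 fell, 2 rose (Rpl36a and Rplp1) and 16 did not pass, with a list median of -0.33 and camera adjusted p = 2.9e-09. Adjusted over the list alone, 28 fell and 2 rose. Rpl4 stood at -0.69 ± 0.13 and Rpl7 at -0.68 ± 0.26. MHC class II genes, which present antigen to helper T cells, were the other list called (3 of 5 fell, median -0.61, camera adjusted p = 0.00749; 4 when adjusted over the list alone), through RT1-Db1, RT1-DMb and RT1-Ba (-0.61 ± 0.28). Either call was lost in camera with the correlation taken from the data (adjusted p = 0.511 with an estimated correlation) and with the flip arrays multiplied by -1 (0.783 and 0.567), where 2 ribosomal genes rose and 1 fell. Over all alternatives the adjusted p ran from 8.5e-11 to 0.783 for the ribosomal list and from 0.000687 to 0.567 for class II. Of 47 oxidative phosphorylation genes Atp5f1b (-0.42 ± 0.08), Atp5pf (-0.46 ± 0.05) and Ndufb4 (-0.61 ± 0.04) fell and Sdha and Uqcrfs1 (0.28 ± 0.10) rose, without a list call (camera adjusted p = 0.377).

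Camera called none of the lists of blood cell type markers at 2 h. Fry, which tests whether a list moves on balance and does not compare it with other genes, called neutrophil granule (adjusted p = 0.0130) and NK and cytotoxic genes (0.0151) upward and monocyte and macrophage (0.00679), T cell (0.0163) and B cell genes (0.0337) downward. All 8 T cell and all 5 monocyte and macrophage genes lay below 0. Fry was not run with the flip arrays multiplied by -1. There the medians were -0.02 for neutrophil granule, 0.05 for NK and cytotoxic, -0.08 for monocyte and macrophage, -0.07 for T cell and -0.01 for B cell genes. Of 7 neutrophil granule genes S100a9, Lcn2 (0.69 ± 0.33) and Chi3l1 rose, while S100a8 stood at -0.08 ± 0.10. Lcn2 is numbered 2 probes after Csnk2b and was at 0.48 once neighbouring probes were subtracted. Il1r2 rose and Hdc fell among 7 neutrophil surface and oxidase genes. The T cell genes Cd3d (-0.39 ± 0.11) and Lef1 fell (2 of 8; camera adjusted p = 0.125), as did the B cell genes Cd37 (-0.45 ± 0.08) and Blnk (2 of 5) and the monocyte and macrophage gene C1qb (-0.20 ± 0.04, 1 of 5; 2 when adjusted over the list alone). Among 5 NK and cytotoxic genes the granzyme Gzmc (1.17 ± 0.13) and Il2rb (0.42 ± 0.16) rose, with 2 up and 1 down when adjusted over the list alone. Of 15 erythroid genes 6 rose, including the band 3 anion exchanger Slc4a1 (0.81 ± 0.21), Car2 and Alas2, and Hba-a1 fell (camera adjusted p = 0.139). Gp9 rose among 5 platelet genes. Of 16 liver genes Tf rose and Serpina3n fell, the latter at 0.041 once neighbouring probes were subtracted; over the list alone Tf was the single call.

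The counts of the other lists at 2 h also depended on the direction of the flip arrays. Multiplied by -1, they gave 5 up and 1 down for oxidative phosphorylation, 3 up for interferon-stimulated genes, 2 up for MHC class I, without a call by camera, 2 up and 1 down for eicosanoid enzymes and 1 up and 1 down for NF-kappaB and AP-1 factors. Among cell types they gave 4 up and 2 down for erythroid, 2 down for T cell, 1 up for platelet, 1 up for neutrophil surface and 1 up and 4 down for liver genes. Apoptosis regulators had 1 up, and glycolysis and proliferation 1 down each. In the remaining lists limma passed 0 members, with 3 cytokine, 2 chemokine, 2 feedback, 1 adhesion, 1 neutrophil granule and 3 monocyte genes at an unadjusted p under 0.05 and 0 class II, B cell and NK genes.

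In all, 407 probes rose and 513 fell at 2 h, 920 of 7200 (2482 at an unadjusted p under 0.05), which corresponds to 368 genes up and 387 down, of which 14 and 4 changed at least 2-fold. The excess of falls was not stable: scaling gave 687 up and 615 down, quantile normalization 610 and 576, and all arrays with a dye term and the rat as a random block 932 and 904. The count was 510 without 2 h rat 1, 315 without 2 h rat 2 and 592 without 6 h rat 2. Of 78 calls on named genes at 2 h, 51 held with any 1 rat left out, and 27 ended without 2 h rat 2 (adjusted p 0.0622 to 0.205): Cx3cl1, Dusp1, Cebpd, Ier2, Rsad2, Ifi27, Ifi27l2b, Pla2g2a, Arg2, Ptger4, Timp1, Hk1, Slc2a1, Mcl1, Tnfrsf1b, Ccnd1, Fen1, Chi3l1, Hdc, Cd3d, Lef1, Blnk, Car2, Alas2, Add2, Gp9 and Serpina3n. In 15 of the 24 lists the counts were the same when adjusted over the list alone. Median, mean and test differed in sign for 5 lists, namely proinflammatory cytokines, chemokines, MHC class I, adhesion and proteolysis, and glycolysis.

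**Figure D1:**
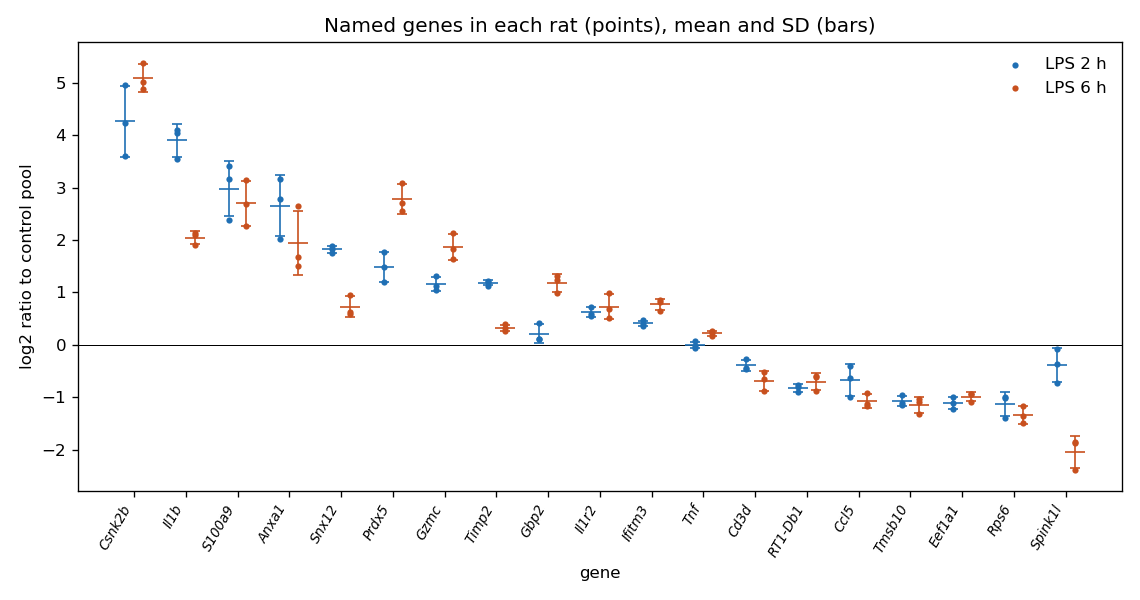
Log2 ratio to the control pool (vertical axis) of 19 named genes (horizontal axis) in each rat at 2 h (blue points) and 6 h (orange points), with bars for the mean and the standard deviation of 3 rats. Csnk2b lies highest at both times, Il1b is lower at 6 h (2.05) than at 2 h (3.90), and Tnf lies near 0 at 2 h.

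At 6 h Csnk2b again had the largest rise among named genes, 5.10 ± 0.26 (SD, n = 3; 34.2-fold; adjusted p = 7.7e-05). Prdx5 rose by 2.78 ± 0.28 (6.88-fold; adjusted p = 7.7e-05), S100a9 by 2.70 ± 0.44 (adjusted p = 0.000347), Il1b by 2.05 ± 0.13 (4.13-fold; adjusted p = 8.4e-05) and the granzyme Gzmc by 1.87 ± 0.25 (3.66-fold; adjusted p = 8.1e-05). The lowest mean among named genes was that of Spink1l, named as a relative of a serine protease inhibitor, at -2.04 ± 0.31 (adjusted p = 0.000205). With the flip arrays multiplied by -1 Csnk2b stood at -0.03, S100a9 at 0.24 and Il1b at 0.22, none past the threshold, Prdx5 (0.29) and Gzmc (0.42) passed, and Spink1l passed with the other sign (0.24).

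The other large rises at 6 h were those of Anxa1 (1.94 ± 0.62), Aldoc (1.63 ± 0.03), Rnf112 (1.59 ± 0.06), the phosphodiesterase Pde2a (1.35 ± 0.18) and the granule proteoglycan Srgn (1.27 ± 0.17). With neighbouring probes subtracted, Rnf112 was at 1.44 and Pde2a, which is numbered 2 probes after Aldoc, at 1.26. The other large falls were those of Rps6 (-1.34 ± 0.17), the oxoprolinase Oplah (-1.23 ± 0.25), prosaposin (Psap, -1.23 ± 0.14), Tmsb10 (-1.15 ± 0.16), the antiproliferative gene Btg1 (-1.12 ± 0.29), Eva1b (-1.12 ± 0.11), Ccl5 (-1.07 ± 0.13), Eef1a1 (-0.99 ± 0.09) and Rpl6 (-0.93 ± 0.07). These 20 genes had adjusted p of at most 0.0334 in 18 of 19 alternatives. The other, with the flip arrays multiplied by -1, is the other reading of the direction and no test of robustness. In it Prdx5, Gzmc and Srgn (0.26) passed with the same sign. Pde2a (-0.13), Spink1l, Rps6 (0.16), Btg1 (0.19) and Eef1a1 (0.20) passed with the other, and the highest adjusted p was 0.911.

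Of 5 cytokine genes Il1b and Tnf (0.22 ± 0.05, adjusted p = 0.00636) rose at 6 h, Tnf standing at 0.038 on the fluor arrays alone (adjusted p = 0.701, in a range over its alternatives of 0.00231 to 0.701) and at -0.18 with the flip arrays multiplied by -1 (adjusted p = 0.0300); over the list alone 3 rose and 1 fell. The chemokine genes Ccl5 and Ccl9 (-0.24 ± 0.03) fell and none of the 8 rose, whereas 2 rose and 2 fell when adjusted over the list alone. Among feedback regulators Anxa1, Il1r2 (0.73 ± 0.24), Dusp1 and the mRNA-destabilising Zfp36 (0.26 ± 0.11) rose and Dusp6 fell, with 5 up and 2 down when adjusted over the list alone. Cebpb (0.35 ± 0.19), of neither family, was the 1 gene of 11 on the NF-kappaB and AP-1 list to pass. Adjusted over the list alone, 2 rose and 3 fell. Nfkbia stood at -0.11 ± 0.05 (adjusted p = 0.0667). Of 18 interferon-stimulated genes 7 rose, including the guanylate-binding protein Gbp2 (1.18 ± 0.17), Ifitm3 (0.78 ± 0.11) and the transcription factor Irf1 (0.46 ± 0.10), and Bst2 and Ifi27l2b fell; camera gave adjusted p = 0.0817, and 10 rose and 3 fell when adjusted over the list alone. Multiplying the flip arrays by -1 gave 4 up and 2 down. Of 6 MHC class I and immunoproteasome genes Psmb9 (0.37 ± 0.12) and B2m (0.36 ± 0.12) rose (camera adjusted p = 0.0795; 3 when adjusted over the list alone), though the 2 probes of B2m gave 0.67 and 0.05. Of 2 measured LPS recognition genes Tlr4, the LPS receptor, rose (0.17 ± 0.09), and Tlr3 did not pass; this list was too short to test, and Tlr4 missed the threshold once neighbouring probes were subtracted.

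The eicosanoid enzymes Alox5 (0.23 ± 0.09) and Alox5ap and the prostaglandin receptor Ptger4 (0.25 ± 0.06) rose at 6 h and Gch1 fell (-0.87 ± 0.08), with 4 up and 1 down when adjusted over the list alone. Stress and oxidative defence genes that passed again all rose, 4 of 18: Txnrd1 (0.24 ± 0.07), thioredoxin (Txn1, 0.21 ± 0.05), Gadd45g (0.25 ± 0.04) and Ddit3, the last at -0.22 on the fluor arrays alone (camera adjusted p = 0.0558). Multiplying the flip arrays by -1 gave 2 up and 5 down. Sod2 stood at 0.12 ± 0.08 (adjusted p = 0.0998). Slc2a1 (0.42 ± 0.05) and Slc2a3 rose among 12 glycolysis genes, and Timp2 (0.32 ± 0.06) and Timp1 rose while Itgb1 and Itgal fell among 10 adhesion and proteolysis genes. Tnfrsf1b was the 1 apoptosis regulator of 7 to rise, and 0 passed when adjusted over the list alone. Among 15 proliferation genes Ccnd1 (0.30 ± 0.12) and Ccnd2 rose and Pcna (-0.35 ± 0.03), Cdk1 (-0.24 ± 0.06), Mcm4 and Stmn1 fell.

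Of 44 ribosomal protein genes 30 fell at 6 h, 2 rose (Rpl41 and Rps29) and 12 did not pass (median -0.37, camera adjusted p = 5.8e-13), among them Rps3 (-0.92 ± 0.12) and Rpl7 (-0.89 ± 0.07); 32 fell and 2 rose when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.511) and with the flip arrays multiplied by -1 (0.0779), where 13 rose, 1 fell and the median was 0.06, and the adjusted p of the alternatives began at 3.4e-14. MHC class II genes were lower (4 of 5 fell, median -0.70, camera adjusted p = 0.0301, or 0.537 with an estimated correlation), with RT1-Ba at -0.85 ± 0.04 and RT1-DMb at -0.74 ± 0.21. Over the list alone 4 fell and Ctss rose. The probe of Ctss held the repeated value on at least 1 array. Without 6 h rat 6 this class II call was lost (adjusted p = 0.0596), as it was after scaling (0.0675) or quantile normalization (0.106) and on the flip arrays alone (0.0830). Over all its alternatives the adjusted p ran from 0.00914 to 0.833, the highest with the flip arrays multiplied by -1. Of 47 oxidative phosphorylation genes 9 fell and 0 rose, including Atp5f1b (-0.71 ± 0.10), Atp5pf (-0.59 ± 0.12) and Cox7a2l (-0.26 ± 0.02), with camera adjusted p = 0.0558 and 10 down when adjusted over the list alone. When the flip arrays were multiplied by -1, 13 rose and 9 fell (camera adjusted p = 0.802) and these 3 took the other sign (0.25, 0.07 and 0.02), Atp5f1b past the threshold.

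Camera called none of the cell type lists at 6 h either, while fry called neutrophil granule (adjusted p = 0.0370) and NK and cytotoxic genes (0.00519) upward and monocyte and macrophage (0.00812), T cell (0.00999) and B cell genes (0.00999) downward. The 2 upward calls rest on few genes: the medians were -0.01 and -0.02, with 4 of 7 and 3 of 5 genes below 0. Of the lists called downward, 3 of 5, 6 of 8 and 3 of 5 genes lay below 0. Fry was not run with the flip arrays multiplied by -1. S100a9, Lcn2 (0.61 ± 0.01) and the defensin Defa5 rose among 7 neutrophil granule genes, with 3 up and 2 down when adjusted over the list alone. Lcn2 stood at 0.34 once neighbouring probes were subtracted (adjusted p = 0.0938, in a range over its alternatives of 0.000298 to 0.569). Il1r2, Alpl and Fcgr2b (0.24 ± 0.09) rose among 7 neutrophil surface genes. Cd3d (-0.69 ± 0.18), Lef1 (-0.28 ± 0.07) and Ccr7 fell among 8 T cell genes (camera adjusted p = 0.195), Cd37 (-0.71 ± 0.03) among 5 B cell genes (2 when adjusted over the list alone), and C1qb (-0.21 ± 0.03) and C1qc among 5 monocyte and macrophage genes. Gzmc and perforin (Prf1, 0.27 ± 0.05) rose among 5 NK and cytotoxic genes. Among 15 erythroid genes Gata1 rose and the globin genes Hbb-b1 (-0.33 ± 0.07), Hbb and Hba-a1 fell, with 4 up and 3 down when adjusted over the list alone; Hba-a1 stood at 0.010 on the flip arrays alone. Of 5 platelet genes 0 passed limma's threshold (3 at an unadjusted p under 0.05), against 1 up and 2 down when adjusted over the list alone. The liver genes Orm1 and Serpina1 rose, and 0 of 16 passed when adjusted over the list alone (7 at an unadjusted p under 0.05). The liver list was not called (camera adjusted p = 0.289), but it was called upward on the flip arrays alone (0.00225, median 0.18) and downward with the flip arrays multiplied by -1 (0.00412, median -0.11, 7 of 16 lower), in a range over its alternatives of 0.00225 to 0.611.

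Most other list counts at 6 h changed as well with the flip arrays multiplied by -1. Erythroid genes then had 6 up and 2 down, NF-kappaB and AP-1 factors 2 up and 4 down, apoptosis regulators 3 up and 2 down, glycolysis 3 up and 2 down, MHC class I 4 up, proliferation 4 down and class II 1 down. Cytokines had 2 down, chemokines 1 up, adhesion and proteolysis 2 down, T cell genes 2 down, neutrophil granule genes 1 up and 2 down and platelet genes 1 up. Feedback regulators, eicosanoid enzymes, neutrophil surface, B cell and NK genes had 1 up and 1 down each. Of the monocyte and macrophage genes limma passed 0 (0 at an unadjusted p under 0.05).

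At 6 h 415 probes rose and 613 fell, 1028 of 7200 (2559 at an unadjusted p under 0.05), or 327 genes up and 422 down, of which 13 and 8 changed at least 2-fold. The excess of falls turned to 913 up and 798 down on the flip arrays alone, 1312 and 1094 with the flip arrays multiplied by -1, and 630 and 593 with each time fitted alone. The probe count was 311 without 6 h rat 2, 403 without 6 h rat 4 and 377 without 6 h rat 6. Of 78 calls on named genes at 6 h, 50 held with any 1 rat left out. Without 6 h rat 2, 25 ended (adjusted p 0.0555 to 0.233): Tnf, Ccl9, Dusp1, Cebpb, Psmb9, Tlr4, RT1-DMa, Alox5ap, Itgb1, Timp1, Itgal, Ddit3, Slc2a3, Tnfrsf1b, Ccnd2, Lcn2, Alpl, C1qc, Lef1, Ccr7, Gata1, Hbb, Hba-a1, Orm1 and Serpina1. B2m ended without 6 h rat 4 or 6 h rat 6 and Defa5 and Ndufb4 without 6 h rat 6, in the ranges 0.0568 to 0.189 and 0.0528 to 0.164. Median, mean and test differed in sign for 6 lists, namely chemokines, NF-kappaB and AP-1 factors, proliferation, neutrophil granule, NK and cytotoxic, and platelet genes.

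**Figure D2:**
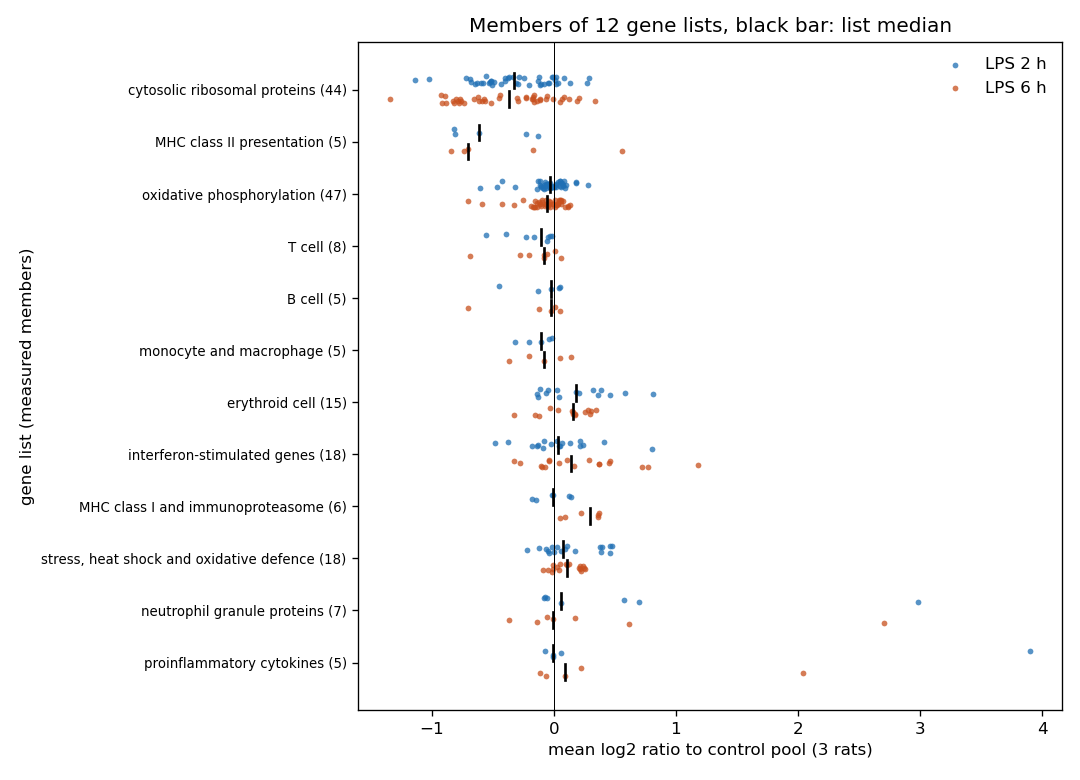
Mean log2 ratio to the control pool (horizontal axis) of each measured member of 12 gene lists (vertical axis, number of members in brackets) at 2 h (blue) and 6 h (orange); each point is a gene, averaged over 3 rats, and each black bar is a list median. The ribosomal protein medians lie at -0.33 and -0.37 and the MHC class II medians at -0.61 and -0.70, while S100a9 and Il1b stand apart from the other members of their lists.

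Between the times, Il1b was lower at 6 h than at 2 h by -1.86 (SE 0.15, n = 3 rats per time; adjusted p = 0.00735), and Spink1l (-1.65, SE 0.20, adjusted p = 0.0265), Snx12 (-1.10, SE 0.10, adjusted p = 0.011) and the metalloproteinase inhibitor Timp2 (-0.86, SE 0.05, adjusted p = 0.00201) were lower as well. Prdx5 (1.30, SE 0.18, adjusted p = 0.0408) and the interferon-stimulated gene Gbp2 (0.97, SE 0.11, adjusted p = 0.0265) were higher at 6 h. The aldo-keto reductase AKR1C3l1 fell at 2 h (-0.38 ± 0.05) and rose at 6 h (0.30 ± 0.03), a difference of 0.68 (adjusted p = 0.00307). Tsc22d1 rose at 2 h (0.40 ± 0.15) and fell at 6 h (-0.36 ± 0.07), a difference of -0.76 (adjusted p = 0.0225).

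The further genes higher at 6 h were Ywhae (0.85), Rpp30 (0.55), the carbonic anhydrase Car4 (0.49), Arhgap30 (0.47), Ap2s1 (0.46), Tmbim4 (0.42), Prl8a2 (0.40) and Herc6 (0.37), and those lower were Rcn1 (-0.48) and Gprc5a (-0.33). Ap2s1 dropped out of 1 alternative and passed in 6 of its other 17. At a difference of 0.46 it was not among the flatter probes, so its probe held the repeated value on at least 1 array. That value differed between arrays (-0.67 to 0.31 at 2 h and -0.29 to 0.53 at 6 h). Part of the difference of Ap2s1 may therefore be no measured change. Tnf differed by 0.22 (adjusted p = 0.107), Sod2 by 0.06 (0.710) and Nfkbia by -0.12 (0.319), none of which passed. Interferon-stimulated genes were higher at 6 h as a list (Gbp2 and Herc6 of 18 passed, 5 when adjusted over the list alone; median 0.11, camera adjusted p = 0.00837). Ribosomal protein genes were lower (median -0.11, camera adjusted p = 0.000265), although 0 of 44 passed with limma over all genes (12 at an unadjusted p under 0.05) and 8 did when adjusted over the list alone. Either call was lost with the correlation taken from the data (adjusted p = 0.537 with an estimated correlation). The interferon call was also lost on the fluor arrays alone (adjusted p = 0.188) and after neighbouring probes were subtracted (0.110), and the ribosomal call on the fluor arrays alone (0.687) and after scaling (0.0675). Over all alternatives the adjusted p ran from 0.00239 to 0.833 for the interferon list, the highest with the flip arrays multiplied by -1, and from 6.8e-07 to 0.687 for the ribosomal list. The ribosomal list was called in the other direction with the flip arrays multiplied by -1 (median 0.11, adjusted p = 2.7e-05). Outside the interferon list, Il1b and Timp2 were the list members that passed, and 7 lists had the same counts when adjusted over the list alone. Median, mean and test differed in sign for 8 lists, namely chemokines, feedback regulators, eicosanoid enzymes, adhesion and proteolysis, stress and oxidative defence, monocyte and macrophage, T cell and liver genes.

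Of 7200 probes 8 were higher and 7 lower at 6 h than at 2 h (1058 at an unadjusted p under 0.05), or 13 and 7 genes, against 0 higher and 2 lower after scaling and 2 and 3 after quantile normalization. The 15 probes became 154 without 2 h rat 3, 7 and 8 without 2 h rats 1 and 2, and 4 and 6 without 6 h rats 2 and 4. Of the 18 named genes Timp2 and AKR1C3l1 passed with any 1 rat left out. Without 6 h rat 2 all other 16 calls ended (adjusted p 0.0554 to 0.154), that on Il1b among them, whose adjusted p ran from 0.000203 to 0.802 over its alternatives. None of the 18 passed with the flip arrays multiplied by -1, where Il1b stood at -0.08.

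Across 3939 genes the changes at 2 h and 6 h had a Pearson correlation of 0.744 and a Spearman correlation of 0.633, a description, since genes are not independent replicates. Pairs of a 2 h and a 6 h rat gave 0.560 to 0.698 (9 pairs). Of the genes past the threshold, 134 rose at both times against 30.5 for independent lists, and 255 fell at both against 41.5. When the flip arrays were multiplied by -1, 249 rose at both (58.5 for independent lists) and 182 fell at both (45.3), of which 21 and 6 were genes shared with the values as deposited. In the values as deposited only 1 gene, Tsc22d1, rose at 2 h and fell at 6 h, and 6 did the reverse. With the flip arrays multiplied by -1 these counts were 0 and 1. These overlaps are between groups treated as different rats and measured against different pools. Both times hold a rat labelled 2, and the labels do not say whether it is 1 animal. The tests at the 2 times still share 1 estimate of the spread per gene, so a gene of small spread passes more easily at both. The counts for independent lists leave this out.

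**Figure D3:**
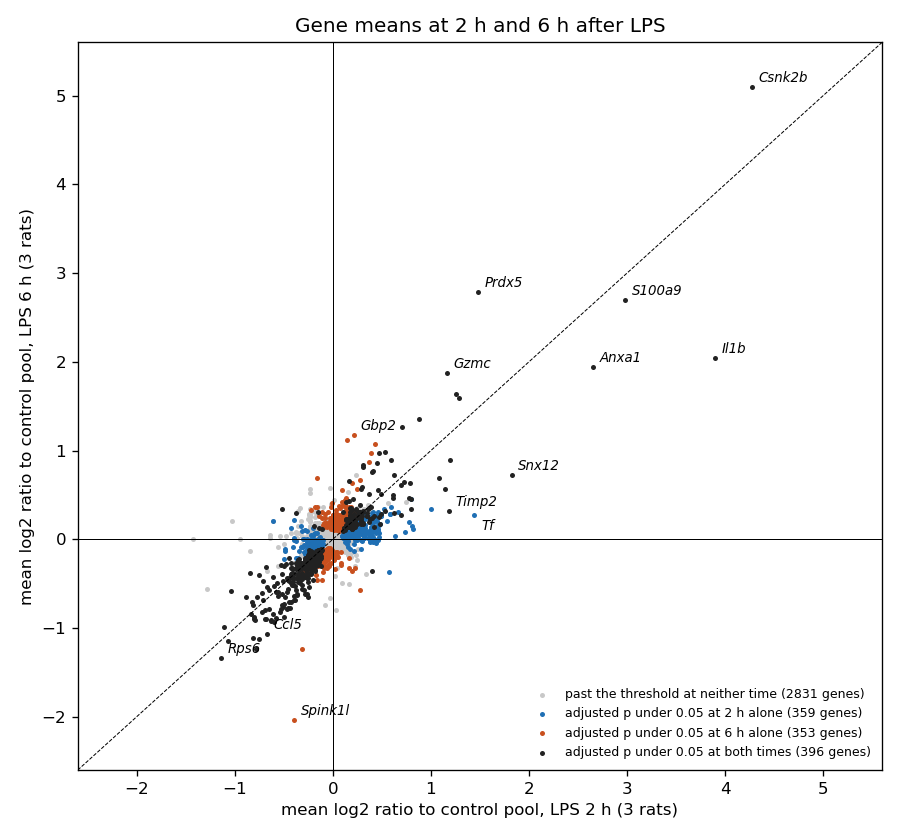
Mean log2 ratio to the control pool of 3939 genes at 2 h (horizontal axis) and 6 h (vertical axis), each point a gene averaged over 3 rats per time and coloured by the times at which it passed the threshold; the dashed line marks equal values. Of these genes 396 passed at both times, 359 at 2 h alone and 353 at 6 h alone; Il1b and Snx12 lie below the line and Prdx5 and Gbp2 above it.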

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

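The results below differed between the 2 times by limma's contrast or by camera; the tests of the control pools and of the other splits of the rats were planned, and those with flip arrays multiplied by -1 were chosen after the data were seen. Higher at 6 h than at 2 h were Prdx5 (1.30), Gbp2 (0.97), Ywhae (0.85), AKR1C3l1 (0.68), Rpp30 (0.55), Car4 (0.49), Arhgap30 (0.47), Ap2s1 (0.46), Tmbim4 (0.42), Prl8a2 (0.40) and Herc6 (0.37). The probe of Ap2s1 held the repeated value on at least 1 array. Lower at 6 h were Il1b (-1.86), Spink1l (-1.65), Snx12 (-1.10), Timp2 (-0.86), Tsc22d1 (-0.76), Rcn1 (-0.48) and Gprc5a (-0.33). Over all probes 15 differed, and 2 gene lists did, interferon-stimulated genes upward and ribosomal protein genes downward. Both list calls were lost in camera with the correlation taken from the data (adjusted p = 0.537 with an estimated correlation). With the flip arrays multiplied by -1, 0 probes differed (limma; 838 at an unadjusted p under 0.05) and the ribosomal list was called upward (median 0.11). Groups of 3 rats are too small to test a single rat as standing apart.

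A change of the LPS response with time and a difference between the control pools cannot be told apart for these genes and lists. The pools were made per time, and 0 of the 6 rats were hybridised against the pools of both times. The 10 splits of the 6 rats into 3 and 3 are too few for a share under 0.05. The real split gave 15 probes and the highest of the others 0 with limma (57 to 649 at an unadjusted p under 0.05, against 1058 in the real split), so 1 of the 10 splits gave as many. For gene lists the real split gave 2 and the highest of the others 3, and 3 of the 10 splits gave as many.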

How the results depend on the processing

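Settings with flip arrays multiplied by -1, without probes at the repeated value or minus neighbouring probes were chosen after the data were seen. The first of these is the other reading of the direction. If the deposited direction holds, a loss in it does not count against a call. The planned filter on missing values was not run because no value was missing. No paired analysis was possible because the 2 times share fewer than 2 rat numbers. With no intensities at hand, signal over background could not limit the probes used. Where no reason is given, the cause was not tested.

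The 920 probes at 2 h became 1883 on fluor arrays alone (794 of the 920 among them), 301 on flip arrays alone (213 shared), 1836 with arrays as observations, a dye term and the rat as a random block, 376 with each time fitted alone and 103 with at least 1.5-fold as a further condition. With flip arrays multiplied by -1 they were 767, of which 120 were among the 920. The 1028 probes at 6 h became 1859, 1711 and 1833 in the first 3 of these settings, 1223 with each time fitted alone, 128 with at least 1.5-fold, and 2406 with flip arrays multiplied by -1 (291 shared). The 15 probes between the times became 2 after scaling, 5 after quantile normalization, 2 on fluor arrays alone, 8 on flip arrays alone, 292 with the block, 25 with robust spread, 34 without probes at the repeated value, 25 minus neighbouring probes, and 0 with flip arrays multiplied by -1 (limma; 838 at an unadjusted p under 0.05). Leaving out 1 rat gave 315 (without 2 h rat 2) to 765 at 2 h, 311 (without 6 h rat 2) to 1301 at 6 h, and 4 (without 6 h rat 2) to 154 (without 2 h rat 3) between the times. The 2 rats left at a time were assumed to vary like the others.

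Camera called 2 lists in each contrast. At 2 h it called 0 with an estimated correlation and with flip arrays multiplied by -1 (3 at an unadjusted p under 0.05 in either case), and 1 without probes at the repeated value, where class II fell below 5 measured members. At 6 h it called 1 after scaling, 1 after quantile normalization, 5 with each time fitted alone, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 1 with flip arrays multiplied by -1, the liver list, downward, and neither of the 2, and 1 without probes at the repeated value. Between the times it called 1 after scaling, 0 on fluor arrays alone (3 at an unadjusted p under 0.05), 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 1 minus neighbouring probes, and 2 with flip arrays multiplied by -1, ribosomal protein genes in the other direction and liver genes downward. Lists called in some alternative but not in the values as reported were erythroid and stress genes at 2 h, stress, interferon-stimulated, MHC class I, oxidative phosphorylation and liver genes at 6 h, and MHC class I and liver genes between the times. Fry, another test, called 15, 14 and 4 lists. Leaving out 1 rat gave 2 to 3 lists at 2 h, 1 (without 6 h rat 6) to 5 (without 6 h rat 4) at 6 h and 2 to 3 between the times.

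The correlation across genes was 0.797 on fluor arrays alone, 0.819 with flip arrays multiplied by -1 and 0.704 to 0.739 with 1 rat left out. Signs turned for Pla2g2a at 2 h on flip arrays alone (0.017), Ptger4 at 2 h on fluor arrays alone (-0.0061), Slc2a1 (-0.0057) and Serpina3n (0.041) at 2 h minus neighbouring probes, Ddit3 at 6 h on fluor arrays alone (-0.22) and Hba-a1 at 6 h on flip arrays alone (0.010). The value of Pla2g2a is the mean of the repeated values of those arrays, so it is no measured turn of sign. With flip arrays multiplied by -1, 63 of 174 calls turned. These were at 2 h Eef1a1 0.079, Gstt1 0.0040, Blvra 0.058, Ccl5 0.17, Dusp1 -0.094, Fosl2 -0.0066, Cebpd -0.10, Ptger4 -0.18, Timp1 -0.059, Slc2a1 -0.052, Ccnd1 -0.16, Rpl4 0.052, Rpl7 0.051, Atp5f1b 0.085, Uqcrfs1 -0.11 and Lcn2 -0.15. At 6 h they were Csnk2b -0.033, Rnf112 -0.059, Pde2a -0.13, Spink1l 0.24, Rps6 0.16, Oplah 0.033, Tmsb10 0.15, Btg1 0.19, Eva1b 0.056, Ccl5 0.25, Eef1a1 0.20, Rpl6 0.21, Tnf -0.18, Il1r2 -0.094, Dusp1 -0.10, Gbp2 -0.0059, Irf1 -0.030, Tlr4 -0.075, RT1-Ba 0.035, RT1-DMb 0.024, RT1-DMa 0.041, Gch1 0.057, Ptger4 -0.049, Alox5 -0.12, Itgal 0.039, Ddit3 -0.47, Slc2a1 -0.072, Ccnd2 -0.11, Rps3 0.16, Rpl7 0.20, Atp5f1b 0.25, Atp5pf 0.066, Cox7a2l 0.023, Defa5 -0.17, Alpl -0.055, Fcgr2b -0.085, Cd37 0.0072, Prf1 -0.067, Orm1 -0.12 and Serpina1 -0.060. Between the times they were Gbp2 -0.15, Ywhae -0.060, Car4 -0.015, Spink1l 0.17, Rcn1 0.012, Gprc5a 0.24 and Herc6 -0.0025. Of 182 results on named genes, 89 lost their call but kept their sign with flip arrays multiplied by -1, 61 lost their call on flip arrays alone, 36 on fluor arrays alone, 28 minus neighbouring probes, 27 after scaling, 24 after quantile normalization, 4 after centring, and 29 to 47 with 1 rat left out.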

Other observations

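All tests in this part were chosen after results were seen, gene families were taken by how their symbols begin, and the genes named here were picked with their values in view. Of 28 genes named Eif or Eef, most of them translation factors but with regulators such as Eef2k, Eif2ak1 and Eif4ebp1 among them, 3 rose and 5 fell at 2 h and 2 rose and 3 fell at 6 h. Eef2, which moves the ribosome along mRNA, fell at 2 h (-0.63) and 6 h (-0.91), Eef1a2 rose at both (0.49 and 0.29), and Eef2k, the kinase that inhibits Eef2, rose at 6 h (0.37). With the flip arrays multiplied by -1, 3 of the 28 rose and 1 fell at 2 h, and 7 rose and 2 fell at 6 h. There Eef2 stood at -0.12 and 0.07, Eef1a2 at -0.05 and -0.13 and Eef2k at -0.06 at 6 h, and of these only Eef1a2 at 6 h passed. Among 15 S100 proteins and annexins S100a9 and Anxa1 rose at both times, whereas S100a10 (-0.77 and -0.65) and S100a4 (-0.42 and -0.32) fell at both. S100a11 rose at 2 h (0.48), Anxa3 rose at 6 h (0.36) and Anxa7 fell at 6 h (-0.45). Multiplying the flip arrays by -1 gave 3 down at 2 h and none up, and 3 up and 1 down at 6 h.

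Of 22 genes named Psm, which are proteasome subunits and, as Psmg1, Psmg4 and Psme3ip1, assembly and binding proteins, 3 rose and 5 fell at 2 h and 3 rose and 6 fell at 6 h, with Psma1 (-0.84 and -0.38) and Psmb4 (-0.35 and -0.23) lower at both times. With the flip arrays multiplied by -1, 2 rose and 1 fell at 2 h, and 4 rose and 3 fell at 6 h. Psma1 then stood at -0.39 and -0.19, past the threshold at 2 h alone, and Psmb4 at -0.07 and 0.07, past it at neither time. The cytochrome P450 genes that passed all rose, 4 of 18 at 2 h and 2 at 6 h, Cyp4f1 (0.78 and 0.63) and Cyp2f4 at both. Cyp4f1 is numbered 2 probes after Anxa1. The P450 genes stood, with the flip arrays multiplied by -1, at 1 up and 3 down at 2 h and 2 up and 8 down at 6 h. Camera called none of 9 families in 27 tests, in either setting. The hypotheses that the Eif and Eef genes were lower with the ribosomal protein genes, that the Psm genes were higher and that S100 proteins and annexins were higher were not borne out, with the higher adjusted p of the 2 times at 0.972, 0.919 and 0.950. For the hypothesis that cytochrome P450 genes did not move as a family, camera's lower adjusted p was 0.260 and the medians were 0.03 and 0.05. A missed threshold does not show that the family stood still, and single members passed.

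Ribosomal protein genes had a median of -0.25 to -0.43 in the 6 rats. The layout of the array, as far as probe numbers give it, is argued against as the whole cause. After neighbouring probes were subtracted the highest median of the 6 rats was still -0.211. On the direction used in the report dye bias is argued against, since the median lay below that of the array on 12 of 12 arrays, fluor and flip alike; it stays open because that direction is unsettled, and a dye effect gives the same picture if the flip ratios were not turned. Fewer lymphocytes stays open as well: in 0 of 6 rats was the median of 13 T and B cell markers (-0.04 to -0.11) as low, but no intensities show these markers above background. For both of these the first condition set counted against the explanation, and it was tightened once the result was known, so a response to LPS stays open beside them as untested.

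Values of probes numbered 2 apart went together (Spearman 0.219 at 2 h and 0.226 at 6 h, against 0.017 and 0.068 for probes 1 apart), as did those 4, 48 and a larger number apart, distances picked from the values. The same gene on neighbouring probes is argued against, since 2697 pairs with different names gave 0.215 and 0 pairs shared a name. Local differences on each array stay open. The deviations of single rats correlated more at 2 than at 1 apart in 4 of 6 rats. At 4, at 48 and at the larger number apart they correlated more than at 1 apart in 6 of 6 rats. Over the rats these correlations ran from 0.13 to 0.30 at 4 apart and from 0.11 to 0.18 at 48. They ran from 0.0077 to 0.13 at 1 apart and from 0.038 to 0.15 at 2. Carry-over from bright spots to the next printed stays open too, and the print order is not known. Probes numbered 2 after a probe raised at least 2-fold exceeded those 2 before it by 0.22 at 2 h (exact two-sided sign-flip p = 0.0690, n = 17) and by 0.06 at 6 h (exact p = 0.662, n = 15). No biological explanation was tested for this pattern.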
